A study of Mus musculus with 4 samples.

How the data were processed

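The study measured DNA methylation by reduced representation bisulfite sequencing (RRBS) in mouse embryonic fibroblasts (MEFs) that carry inducible reprogramming factors. RRBS cuts genomic DNA with the restriction enzyme MspI, selects short fragments and converts unmethylated cytosines with bisulfite, so that reads cover mainly CpG-rich parts of the genome. Per the labels' protocols, fragments of 40 to 220 bp were selected. There were 4 libraries, 1 per group: uninduced control MEFs, and MEFs kept in doxycycline for 96 hours that had gone through an average of 0, 1 or more than 3 divisions. These are called the control, 0-division, 1-division and >3-division libraries. The labels name a growth medium with 10% serum, a doxycycline medium with 15% serum and a serum starvation medium with 0.5% serum, without saying which cohort received the last.

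The authors deposited, for each library, a table of CpG positions with 2 whole-number read counts per CpG, methylated and unmethylated. The order of these deposited counts was settled from the values, because the files have no header. The second number is often 0 beside a larger first number, so it is not a total. In CpG-dense sequence of the control library 58.7% of 476359 CpGs had a first number of 0, so the first number is the methylated count. Positions are on mm9, per the submitters' processing notes; positions on chromosome 1 run to 197193524, past the end of the last chromosome 1 gene of GRCm38 at 195291439. The aligner, the methylation caller, the check of bisulfite conversion and the treatment of duplicate reads are not given in the sources used here. Whether positions count from 0 or from 1 is not given either, so positions are printed as in the deposited tables. No position was listed more than once in a library and no listed positions lay 1 bp apart, so each CpG had a single entry with its strands already combined.

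Methylation levels were computed as methylated reads divided by all reads, in percent, at the 1045368 CpGs covered by at least 10 reads in all 4 libraries, of 2057290 listed in any library. Neighbouring CpGs at most 100 bp apart were joined into clusters of at least 3 CpGs, which gave 99566 clusters with a median of 4 CpGs and a median span of 82 bp. Reads were summed over the CpGs of a cluster. CpG density was the number of CpGs listed in any library within 100 bp on either side: at most 4 was called CpG-poor and at least 12 CpG-dense. The annotation at hand was on GRCm38, so no gene, promoter or exon was assigned to a position, and the promoter and gene list comparisons that had been planned were not made; clusters took their place.

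Each doxycycline library was compared with control, and the >3-division library with the 0-division library, by a two-sided Fisher's exact test on read counts per CpG or cluster with Benjamini-Hochberg adjustment over the features tested. A CpG was called changed at an adjusted p under 0.05 and a difference of at least 20 percentage points, a cluster at an adjusted p under 0.05 and at least 10 points. With 1 library per group these tests compare 2 libraries, not the conditions, and no spread between replicates can be estimated. RRBS reads carry no molecular identifiers here and CpGs on a read are not independent, so p-values are too small, and 95% Wilson intervals of a level cover counting error only. Intervals of mean differences come from 1000 redraws of 1 Mb windows and do not cover the spread between cultures. For each comparison the 5 clusters with the largest gain and the 5 with the largest loss were named. Groups, tests, thresholds, the naming rule and most alternatives were set before the data were examined.

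In simulated data with the real depths of >3-division minus control, the CpG test recovered 2% of falls of 20 points and 28% of falls of 40 points among 1045368 CpGs. The cluster test recovered 64% and 99% of such falls among 99566 clusters, with 5 false calls among the unchanged clusters. These recoveries and false calls hold for counting error alone, without the overdispersion given below, so real false calls may be more. Sampling noise with no change was simulated by drawing reads at each CpG's or cluster's pooled level, and for shared calls also with the overdispersion given below. That second simulation was added after the data were seen.

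Alternatives were a coverage minimum of 5 or 20 reads, thinning each CpG to the lowest of the 4 coverages, leaving out CpGs above the 99.9th percentile of coverage, autosomes only, other minimum differences, centring on features of like level, and cluster gaps of 50 or 200 bp. Added after the data were seen were a difference with equal weight per CpG, means of CpG-dense sites on X and autosomes with pooled reads or weights by control reads, an exact test against the library-wide odds ratio, and division of read counts by the overdispersion between the control and 1-division libraries, which was 1.36 for CpGs and 1.94 for clusters. The library-wide odds ratio is the median, over clusters or CpGs between 20% and 80%, of the odds of methylation in a library divided by those in the library it is compared with. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and plots matplotlib 3.10.9.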

Results

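DNA methylation was measured genome-wide in the initial phase of reprogramming, in secondary MEFs from a hybrid of mouse strains. Secondary MEFs carry doxycycline-inducible reprogramming factors in every cell, so that the drug starts reprogramming in the whole culture. Uninduced cells were set against 3 cohorts held in doxycycline for 96 hours and sorted by how often they had divided. The design asks whether methylation changed in this phase and whether any change went with cell division. Each of the 4 libraries listed between 1734328 CpGs (1-division) and 1807769 CpGs (0-division). The summed read count over CpGs was 84606824 in control, 86782772 in the 0-division library, 84954702 in the 1-division library and 94775128 in the >3-division library. The median coverage of listed CpGs was 35 reads in control, 28 in the 0-division, 34 in the 1-division and 24 in the >3-division library. Each group had 1 library, so no value below has a replicate check.

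Methylation was nearly the same in control, 0-division and 1-division cells and lower in the >3-division library. Over the 1045368 CpGs covered by at least 10 reads in all libraries, the mean methylation level was 42.4% in control, 42.7% in the 0-division, 42.5% in the 1-division and 38.8% in the >3-division library. The difference from control was 0.24 points in the 0-division library (95% interval over 1 Mb windows, 0.22 to 0.26), 0.098 points in the 1-division library (0.083 to 0.12) and -3.62 points in the >3-division library (-3.68 to -3.57). With reads pooled over CpGs in place of equal weight per CpG, the 1-division difference changed sign to -1.44 points and the >3-division difference was -17.1 points. The share of CpGs at or over 80% methylation was 34.2% in control, 33.7% in the 0-division, 34.2% in the 1-division and 27.0% in the >3-division library. Autosomal means of the >3-division library lay between -3.77 and -3.05 points from control, and all 20 chromosomes were below control. Levels of clusters correlated across the genome with r = 0.995 between control and the 1-division library and with r = 0.982 between control and the >3-division library; these are correlations across clusters, which are not independent replicates.

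With equal weight per CpG, the >3-division library differed from control most in CpG-poor sequence, the part of the genome that is methylated in most cells, while with pooled reads the difference was -12.1 points there and -17.8 points at intermediate density. CpG-poor sites averaged 73.4% in control, 73.2% in the 0-division, 73.5% in the 1-division and 66.1% in the >3-division library, a difference from control of -7.29 points in the last (-7.36 to -7.22). At intermediate density the means were 56.9% in control and 53.3% in the >3-division library. CpG-dense sequence, which includes CpG islands and is mostly unmethylated, averaged 7.26% in control and 6.46% in the >3-division library. It averaged 8.08% in the 0-division library, 0.82 points above control (0.80 to 0.84), and 7.31% in the 1-division library. Over all tested CpGs, 21.3% were at 0% in the 0-division library, against 27.5% in control, 28.3% in the 1-division and 28.1% in the >3-division library. Less complete bisulfite conversion of the 0-division library was not tested as a source of its rise and stays open. Among CpGs between 20% and 80% in control, the >3-division library differed by -7.91 points, against 1.28 points in data simulated with no change. Among CpGs at or over 80% in control it differed by -5.96 points, against -1.01 points in the simulation. The >3-division library also held fewer reads at methylated sites: 26% of its reads were methylated, against 44.4% in control. Relative to unmethylated CpGs of like density, the depth of CpGs at or over 80% was 0.461 times that of control in CpG-poor, 0.421 times at intermediate density and 0.425 times in CpG-dense sequence.

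**Figure D1:**
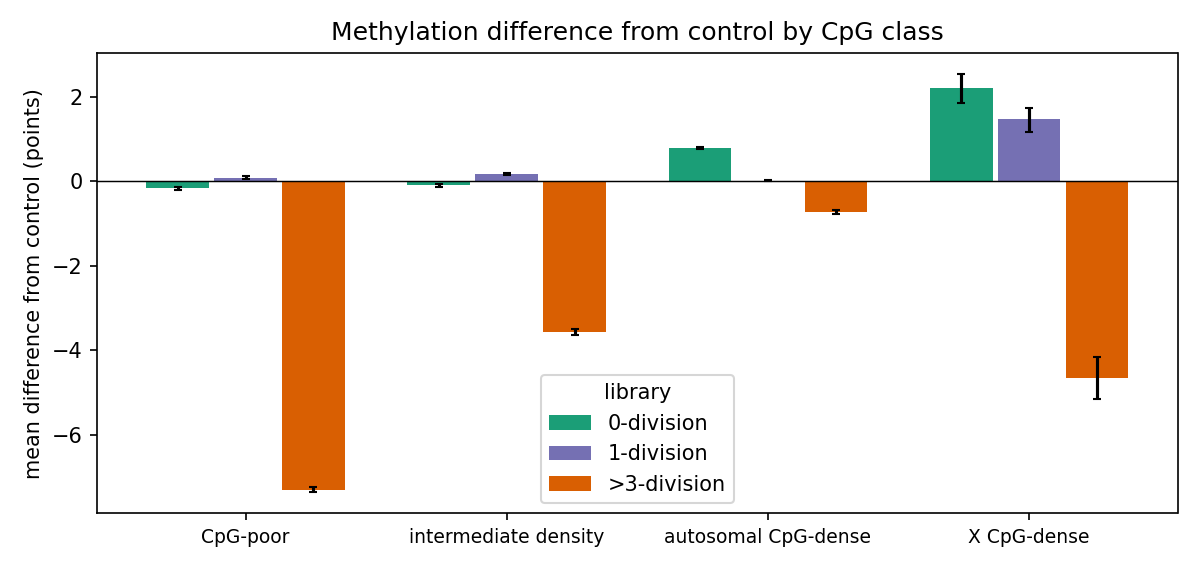
Mean methylation difference from control in percentage points (y axis) for the 3 doxycycline libraries in 4 classes of CpGs (x axis); error bars are 95% intervals from redrawing 1 Mb windows, with 1 library per group. The >3-division library differs from control by -7.29 points in CpG-poor sequence, the 0-division library by -0.17 points and the 1-division library by 0.088 points, and the X CpG-dense class is above control in the 0- and 1-division libraries and below it in the >3-division library.

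The first comparison set cells that had not divided during 96 hours in doxycycline against uninduced control. In this and the next comparisons with control, serum and medium may differ as well as factor induction. Of 99566 clusters, 393 gained and 374 lost at least 10 points in the 0-division library (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). The largest gain was at chromosome 19 from 4042274 to 4042284, 3 CpGs within 11 bp, at 18.4% in control (Wilson interval 9.98% to 31.4%, 49 reads) and 64.9% in the 0-division library (48.8% to 78.2%, 37 reads). A cluster on the X chromosome from 92043394 to 92043399 was at 10.0% in control and 46.2% in the 0-division library, and was at 13.5% and 7.23% in the 1- and >3-division libraries. A cluster on chromosome 13 from 56663632 to 56663664 was at 21.7% of 1069 reads in control and 56.9% of 392 reads in the 0-division library (adjusted p = 4.52e-32, Fisher's exact test), with 30.7% and 27.6% in the other cohorts. Clusters at chromosome 6, 51474014, and chromosome X, 79068051, gained 35.1 and 34.4 points. With equal weight per CpG in place of summed reads, the chromosome 6 gain was 19 points, and at equal depth it was 22.0 points. The largest losses were at chromosome 17 from 31774276 to 31774296, from 45.5% to 5.08%, and at chromosome 6 from 3151553 to 3151575, from 73.8% of 397 reads to 35.3% of 1210 reads. Losses at chromosome 2, 72275592, from 95.6% to 57.1%, at chromosome 8, 72986482, from 37.7% to 0 of 89 reads, which allows up to 4.14% (Wilson), and at chromosome 1, 40754144, from 63.5% to 27.7%, followed. The last difference was -19.97 points with equal weight per CpG. The chromosome 2 difference of -38.4 points was -28.6 points with equal weight per CpG, -20 points at equal depth and -13.5 points with a minimum of 20 reads per CpG. At single CpGs, 47 of 1045368 gained and 66 lost at least 20 points. When read counts were divided by the overdispersion between the control and 1-division libraries, 71 clusters and 54 CpGs were called, and at equal depth 314 clusters and 22 CpGs.

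The second comparison took cells that had divided once on average. They differed from control at fewer sites: 214 clusters gained and 131 lost at least 10 points, and 23 CpGs gained and 16 lost at least 20 points (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). The chromosome 19 cluster at 4042274 again showed the largest gain, with 82.4% (66.5% to 91.7%, 34 reads). Gains at chromosome 7, 17397133, from 54.5% to 91.4%, and at chromosome 8, 11538574, from 34.7% to 70.0%, came next; the same clusters stood at 81.0% and 68.6% in the 0-division library. Clusters at chromosome 13, 73146827, and chromosome X, 159267023, gained 34.0 and 33.7 points. The largest losses were at chromosome 3, 95073628, from 95.2% to 57.6% on 33 reads, and again at chromosome 17, 31774276, from 45.5% to 9.09%. Clusters at chromosome 10, 75322095, and chromosome 15, 79301291, differed by -29.8 and -28.4 points. The chromosome 10 difference was -19.2 points with equal weight per CpG and -18.6 points at equal depth. The cluster at chromosome 1, 22881178, differed by -25.0 points with summed reads and by -9.00 points with equal weight per CpG. Without its CpGs of highest coverage the difference was -1.47 points (unadjusted p = 0.681, Fisher's exact test). When read counts were divided by the overdispersion between these same 2 libraries 17 clusters and 10 CpGs were called, and at equal depth 107 clusters and 9 CpGs.

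The third comparison took cells that had divided more than 3 times. Here 10970 clusters lost and 574 gained at least 10 points, 11.6% of all clusters tested, and 31858 CpGs lost and 904 gained at least 20 points (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). Losses were called in 16.4% of CpG-poor, 11.9% of intermediate and 2.05% of CpG-dense clusters. A cluster under 10% in control cannot lose 10 points, and 82.3% of 19703 autosomal CpG-dense clusters were under 5% there. These shares therefore do not show that CpG-dense sequence was spared. The largest loss was at chromosome 17 from 95007638 to 95007654, from 83.2% in control (75.5% to 88.8%, 119 reads) to 5.56% (1.54% to 18.1%, 36 reads). At chromosome 5 from 130661182 to 130661251 the level was 93.1%, 89.2% and 87.7% in control, 0-division and 1-division cells and 21.7% in the >3-division library (16.4% to 28.1%, 189 reads). At chromosome 5 from 23723819 to 23723850 it was 72.1%, 79.9%, 79.3% and 4.10% in the same order, the last on 390 reads. Clusters at chromosome 10, 68712496, and chromosome 4, 125747492, differed by -65.5 and -64.9 points. In each of these 5 clusters the 0-division and 1-division levels were at or above 66.2%. The largest gain was again the chromosome 19 cluster at 4042274, with 95.5% on 66 reads. Gains at chromosome 2, 170046734, from 19.7% to 54.0%, at chromosome 11, 54214466, from 33.3% to 67.2%, at chromosome 9, 121799814, from 35.8% to 69.2%, and at chromosome 17, 63394809, from 21.2% to 53.8%, followed. Relative to the library-wide odds ratio of 0.697, which moves an average cluster with the whole library, 3791 clusters were lower and 3177 higher by at least 10 points, and relative to the odds ratio of 0.63 over CpGs 11543 CpGs were lower and 5500 higher by at least 20 points (exact conditional test, adjusted p under 0.05). When read counts were divided by the overdispersion, 5376 clusters were lost and 155 gained, and 18715 CpGs were lost and 329 gained. At equal depth 7851 clusters were lost and 288 gained, and 17678 CpGs were lost and 398 gained.

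**Figure D2:**
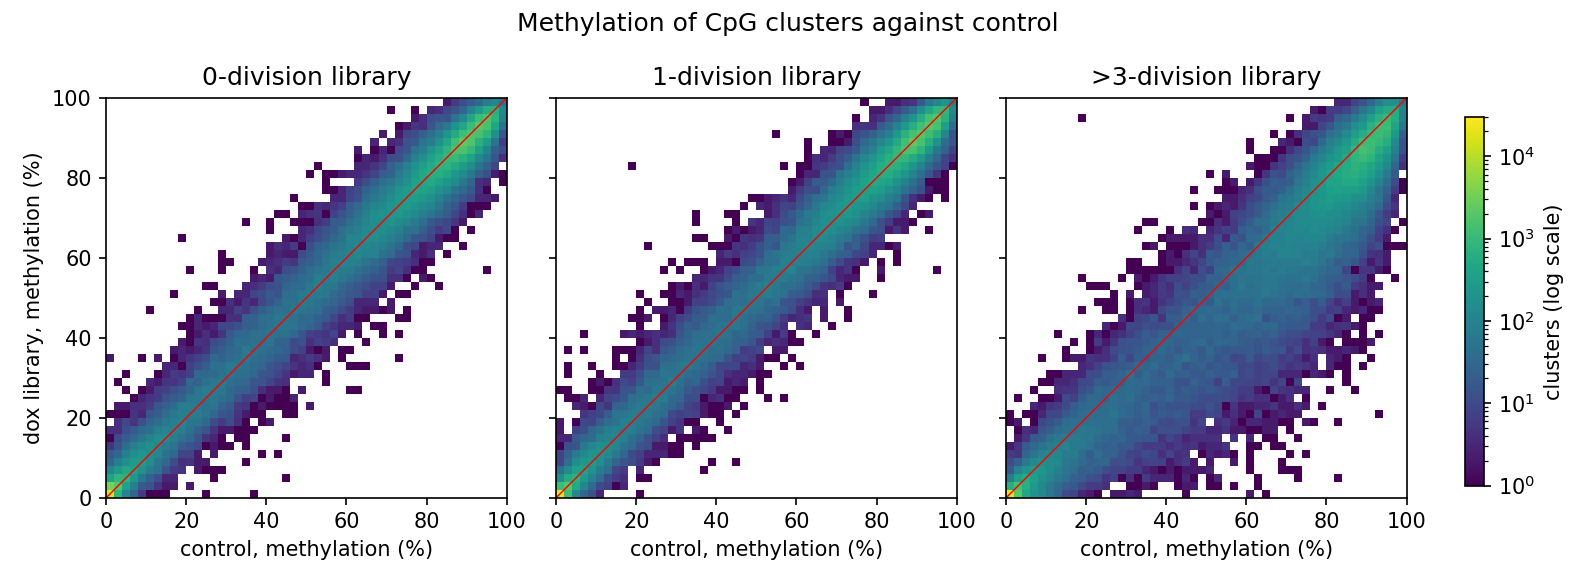
Methylation of 99566 CpG clusters in each doxycycline library (y axis, percent) against control (x axis, percent), as a two-dimensional histogram with the number of clusters on a log colour scale; the red line marks equal levels. The 0- and 1-division libraries lie close to the line, and the >3-division library has a broad tail below it, with 10970 clusters lost and 574 gained.

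**Figure D3:**
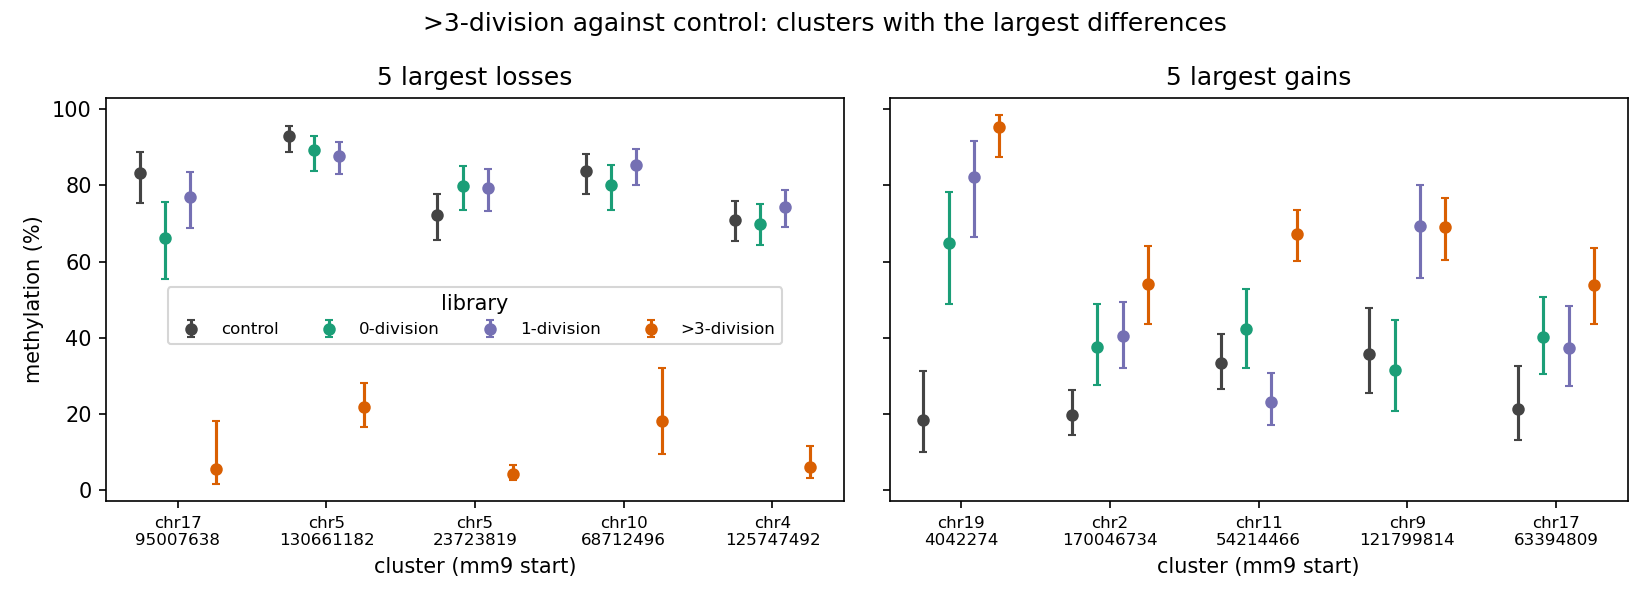
Methylation level (y axis, percent) of the 5 clusters with the largest loss and the 5 with the largest gain in the >3-division library against control (x axis, mm9 position); points are the 4 libraries and bars 95% Wilson intervals, which cover counting error only. At the 5 lost clusters the control, 0-division and 1-division libraries lie at or above 66.2% and the >3-division library at or below 21.7%.

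Within the induced cells, the >3-division library was compared with the 0-division library, which shares the drug but not the divisions. Which cohort received the starvation medium is not given, so serum may differ between these libraries as well. Here 11166 clusters were lower and 611 higher by at least 10 points, and 33636 CpGs were lower and 928 higher by at least 20 points (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). The largest losses were at chromosome 5, 23723819, from 79.9% to 4.10%, at chromosome 17, 66011140, from 73.2% to 0 of 57 reads, which allows up to 6.31% (Wilson), and at chromosome 8, 95201286, from 74.3% to 2.5%. The last cluster stood at 46.3% in control and 42.3% in the 1-division library. Clusters at chromosome 4, 125747365, and chromosome 5, 133951127, differed by -71.4 and -69.8 points and stood at 7.44% and 6.84% in the >3-division library. The largest gains were at chromosome 15, 76003506, from 39.7% to 85.4%, at chromosome 16, 90349721, from 19.8% to 59.4% (20.7 points with equal weight per CpG), and at chromosome 9, 121799814, from 31.5% to 69.2%. The clusters at chromosome 4, 149377574 and 136353824, were higher by 36.0 and 34.2 points. Relative to the library-wide odds ratio of 0.70, 4005 clusters were lower and 3645 higher by at least 10 points, and relative to 0.641 over CpGs 13029 CpGs were lower and 5364 higher by at least 20 points. When read counts were divided by the overdispersion, 6033 clusters were lower and 175 higher, and 20321 CpGs were lower and 339 higher. At equal depth 8317 clusters were lower and 332 higher, and 18143 CpGs were lower and 425 higher.

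CpG-dense sequence on the X chromosome, which in female cells is methylated on the inactive copy, set the libraries apart more than CpG-dense sequence on autosomes did. X CpG-dense sites averaged 25.3% in control, 27.5% in the 0-division, 26.7% in the 1-division and 20.6% in the >3-division library. The differences from control were 2.21 points (1.85 to 2.54), 1.46 points (1.17 to 1.74) and -4.66 points (-5.14 to -4.15), against 0.79, 0.018 and -0.72 points on autosomes. With pooled reads the 0- and 1-division differences on X changed sign, to -0.304 and -0.631 points, and the >3-division difference was -16.3 points. With each CpG weighted by its control reads in both libraries they were 1.65, 1.13 and -5.07 points. Of 618 X CpG-dense clusters, 53.6% lay between 5% and 60% in control, 66.3% in the 0-division, 62.1% in the 1-division and 11.3% in the >3-division library. On autosomes the share between 5% and 60% was 10.3%, 12.3%, 10.3% and 9.56% in the same order. CpG-poor sites on X were at 79.2% in control and 72.0% in the >3-division library, a difference close to that of autosomal CpG-poor sites (-7.20 against -7.29 points). Among clusters that gained at least 10 points, X held 62 of its 4476 clusters in the 0-division library, against 331 of 95090 on autosomes, and 28 against 186 in the 1-division library. These differences have no replicate check.

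**Figure D4:**
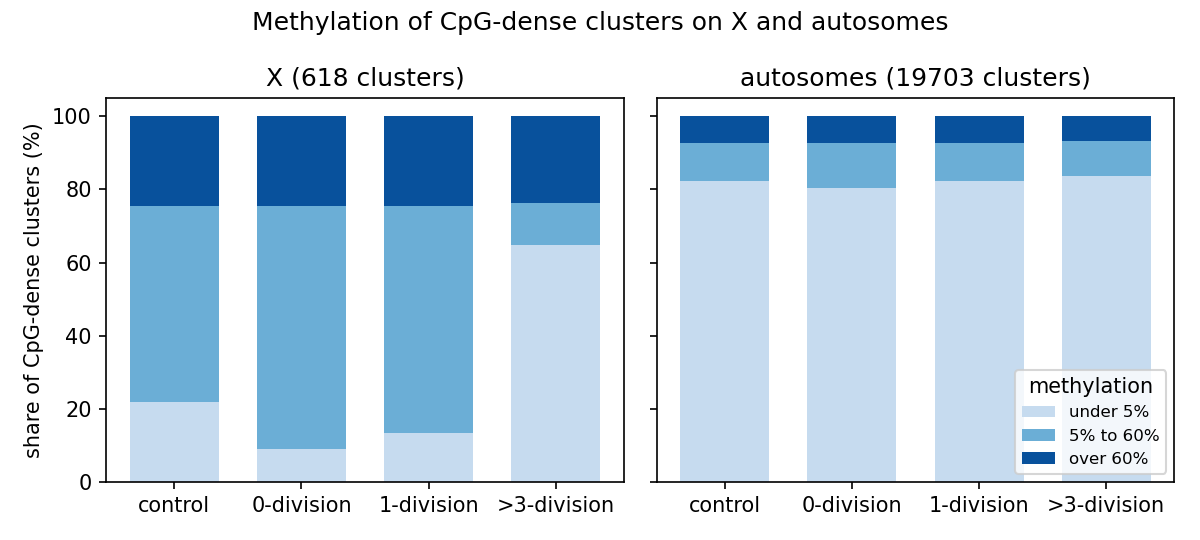
Share of CpG-dense clusters (y axis, percent of clusters) under 5%, from 5% to 60% and over 60% methylated in each library (x axis), for 618 clusters on X and 19703 on autosomes. On X the middle class takes 53.6% of clusters in control and 11.3% in the >3-division library, while on autosomes it takes 10.3% and 9.56%.

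The last comparison asked whether the cohorts differed from control at the same places. Across clusters the differences from control correlated with r = 0.473 between the 0- and 1-division libraries, where unchanged libraries that share a control gave 0.483 in simulation. The correlation was 0.265 between the 0- and >3-division libraries (0.437 simulated) and 0.212 between the 1- and >3-division libraries (0.44 simulated). The covariance was 7.0 square points for the 0- and 1-division libraries against 4.44 simulated, 7.66 against 4.44 for the 0- and >3-division libraries, and 5.93 against 4.41 for the 1- and >3-division libraries. These simulated correlations and covariances hold counting error alone, without the overdispersion of 1.94 for clusters. A covariance above the simulated value therefore does not show shared change. The 0- and 1-division libraries shared 52 gained and 26 lost clusters, the 0- and >3-division libraries 39 and 211, and the 1- and >3-division libraries 12 and 87. Independent lists would share 0.845 and 0.492, 2.27 and 41.2, and 1.23 and 14.4 clusters in the same order, but all lists use the same control library. Unchanged libraries simulated against 1 control shared 0 clusters in 20 simulations with counting error alone. With the overdispersion between the control and 1-division libraries they shared 18.4 gained and 22.2 lost clusters on average for the first pair (highest 28 and 36), 16.2 and 20.1 for the second (highest 26 and 29) and 17.1 and 20.4 for the last (highest 22 and 30). The 26 lost clusters of the first pair and the 12 gained clusters of the last were thus not above the highest count of unchanged libraries. Since the overdispersion was measured on the 1-division library, real change there would raise these simulated counts. The simulations otherwise leave out real changes, the library-wide fall among them, and part of any excess may come from the shared control. Clusters are not independent replicates.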

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

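Tests of read depth at methylated sites, of bisulfite conversion, of stepwise loss, of neighbouring clusters, of the 1-division library at lost clusters and all tests on the X chromosome were chosen after the results they bear on were seen, while those at equal reads and of single-CpG variants were set before.

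The >3-division library differed from the 0-division library by -3.87 points over all CpGs, while the 0-division library was above control; this opposite direction was not tested against replicates. The direct test between those 2 libraries called 34564 CpGs and 11777 clusters. On X CpG-dense sequence the same difference was -6.87 points, also untested.

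The fall across the genome. Clusters were put in 7 bins by their level in the 0- and 1-division libraries. From 5% up, the median odds of methylation in the >3-division library were 0.727 to 0.769 times those of control. In the bin under 5% the value was 0.661, but it is partly set by depth. A small constant was added to each count, and the >3-division library was deeper there (median 111 against 67.3 reads per CpG). The mean levels of that bin were 1.16% in control and 0.882% in the >3-division library. The tables argue against better bisulfite conversion, since the fall in CpG-poor sequence was 8.21 times the control level of 0.887% at unmethylated CpG-dense sites. Read depth stays open in part. Reads simulated at the real depths with no change gave a mean difference of -0.00097 points, so counting error alone does not give the fall. The mean difference at equal reads per CpG was -3.63 points, but random thinning leaves expected levels as they are and decides nothing. Depth that goes with methylation stays open. The difference was -4.13 points with a minimum of 5 reads and -3.21 points with a minimum of 20. A loss that adds up from the first division stays open as well, because 1-division minus 0-division in CpG-poor sequence was 0.26 points with equal weight per CpG (0.22 to 0.29 over windows) and -0.255 points with pooled reads, between single libraries. Loss of methylated molecules during library making also stays open and has support in the depth, because methylated CpGs held at most 0.461 times the relative depth of control in any density class, while the 0- and 1-division libraries ranged from 0.912 to 0.969. The odds of methylation from 5% up fell less, to 0.727 to 0.769 times control, so the depth and the odds differ in size. Whether such a loss gives the whole fall was not tested. A real fall that sets in after more divisions is untested, because cohort and library are the same thing here.

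Local losses. Beyond each library's own odds ratio, 831 clusters of the >3-division library lay at least 20 points below each of the 3 other libraries and 107 above, while the same rule gave 7 and 5 in the 0-division, 1 and 2 in the 1-division and 2 and 1 in the control library. Duplicate reads of single fragments are argued against as the source of all these losses. Of 423 neighbouring clusters 200 bp to 2 kb away, 24.1% were also at least 10 points low. In 1000 lists matched on control level alone the median was 7.96% and the highest 13.5%. Not every loss had such a neighbour and most neighbours were not low, so duplicates stay open for single clusters. Variants at single CpGs are argued against, since a median of 94.1% of a cluster's CpGs were low. The lower depth of this library stays open. At equal reads 85.0% of the losses were still at least 20 points low, but random thinning leaves expected levels as they are and cannot decide this. A loss already under way after 1 division at these clusters as a set is argued against, since at the 1469 clusters lost beyond the odds ratio against control alone, chosen without the 0- and 1-division libraries, the median of 1-division minus 0-division was 1.10 points against 0.39 in matched lists (highest 0.815). This says nothing of single clusters. Over all 99566 clusters, 87 were called lost by at least 10 points against control in both the 1- and >3-division libraries. Unchanged libraries simulated with the overdispersion shared 20.4 on average (highest 30). How many of the 87 lie among the local losses was not counted. Loss of methylated molecules during library making was not tested for these clusters and stays open. A local, division-linked loss of methylation during reprogramming may also underlie the local losses and remains a hypothesis from a single library. The labels do not say which cohort was serum-starved, so division may not be the only difference.

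The X chromosome. At 414 X CpG-dense clusters between 5% and 60% in the 0- and 1-division libraries, the median odds ratio of the >3-division library to control was 0.234. This was below all 1000 matched autosomal lists (median 0.849, lowest 0.789), so the library-wide odds ratio does not account for it. Loss of methylated molecules during library making was not tested on X and stays open for this fall. Over all CpG-dense sites, methylated ones included, the X to autosome depth relative to control was 1.06, 1.01 and 0.769 in the 0-, 1- and >3-division libraries (0.728 to 0.807 in the last). In the 0- and 1-division libraries the rise on X exceeded that on autosomes by 1.42 points or more, which argues against unconverted cytosines as the source of the excess on X. Pooled reads turned this rise to -0.304 and -0.631 points, whereas weighting each CpG by its control reads in both libraries left it at 1.65 and 1.13 points, so the turn came with how each library's reads were spread over CpGs. A different share of cells with 2 X chromosomes could give both patterns and stays open, because its 2 measures of X depth point in opposite ways. At methylated CpG-poor sites the X to autosome depth relative to control was 0.975, 0.953 and 1.09 in the 0-, 1- and >3-division libraries, and at unmethylated CpG-dense sites it was 1.13, 1.07 and 0.90. No autosome left the range 0.963 to 1.04 in either class. A change in the number of X copies would move both measures the same way, so at least 1 of them reflects something else, and the tables do not show which. A change of the inactive X within cells, a candidate given by the design's factor induction, is untested.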

How the results depend on the processing

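Alternatives chosen after the data were seen were equal weight per CpG within clusters, the library-wide odds ratio, division of reads by the overdispersion, and, for CpG-dense sites on X and autosomes, pooled reads and weights by control reads. No paired analysis was possible because each group has 1 library. Promoters and gene lists, with all their alternatives, were not run for lack of an annotation on mm9, nor were tests by strand, because the tables combine strands. Where no reason is given below, the cause was not tested.

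The >3-division library was below control and below the 0-division library in mean methylation, and had more lost than gained CpGs and clusters, under every alternative run. The 40 named changes kept their direction in all 213 alternative settings, but many of these settings could not change it. For many clusters the lower coverage minimum, leaving out the CpGs of highest coverage or keeping autosomes only left the reads as they were. The higher coverage minimum gave no value for many of the clusters. The count of 213 therefore overstates how far direction was tested. Among these settings 1, for the cluster at chromosome 1, 22881178, gave an unadjusted p at or over 0.05. It was 0.681 (Fisher's exact test), with a difference of -1.47 points, when the CpGs of highest coverage were left out.

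Counts are given in the order 0-, 1- and >3-division against control and >3- against 0-division. With a minimum difference of 40 points, 30, 10, 13267 and 13698 CpGs were called. At equal depth these were 22, 9, 18076 and 18568, and with reads divided by the overdispersion 54, 10, 19044 and 20660, where fewer reads enter each test. Leaving out the CpGs of highest coverage gave 25 CpGs for the 1-division library. Against the library-wide odds ratio 17043 CpGs differed between >3-division and control and 18393 between >3- and 0-division, and for clusters 6968 and 7650. A minimum difference of 5 points gave 1523 clusters in the 0-division and 608 in the 1-division library. A minimum of 20 points gave 102, 63, 3907 and 3872 clusters. At equal depth 314 and 107 clusters were called for the 0- and 1-division libraries, and with reads divided by the overdispersion 71, 17, 5531 and 6208 in the 4 comparisons.

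Mean differences are given in points. Pooling reads over CpGs weights deeply covered sites, which in the >3-division library are the unmethylated ones. It gave -17.1 for >3-division minus control over all CpGs, -12.1 in CpG-poor, -17.8 at intermediate density, -4.09 in CpG-dense sequence and -14.4 on X, and -17.4 for >3- minus 0-division, so that the order of CpG-poor and intermediate sequence turned. For 1-division minus control it reversed the sign, with -1.44 over all CpGs, -0.542 in CpG-poor, -1.21 at intermediate density, -0.312 in CpG-dense sequence and -1.40 on X. For 0-division minus control it gave 0.269 over all CpGs, -0.286 in CpG-poor, -1.81 at intermediate density and 0.445 in CpG-dense sequence, and reversed the sign on X with -1.32. The small mean differences of the 0- and 1-division libraries thus depend on how CpGs are weighted. In CpG-dense sequence on X, pooled reads gave -0.304, -0.631 and -16.3 for the 0-, 1- and >3-division libraries minus control, the first pair reversed in sign, and on autosomes 0.43, -0.308 (reversed) and -3.84. With each CpG weighted by its control reads in both libraries, the X values for the 0- and 1-division libraries were 1.65 and 1.13, and the autosomal values for the 3 libraries were 0.642, 0.0542 and -1.08.

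With each library's own CpGs the differences from control were 0.391, 0.439 and -7.87 in the 0-, 1- and >3-division libraries, and -8.26 between the last and the 0-division library. With a minimum of 5 reads the 0-division library differed by -0.257 in CpG-poor, -0.137 at intermediate density and 0.948 in CpG-dense sequence. The 1-division library then differed by 0.134 over all CpGs, 0.137 in CpG-poor, 0.214 at intermediate density and 0.0689 in CpG-dense sequence. The >3-division library differed by -4.13 over all CpGs, -7.84 in CpG-poor, -4.26 at intermediate density, -0.98 in CpG-dense sequence and -6.31 on X, and by -4.37 from the 0-division library. With a minimum of 20 reads the 0-division values were -0.122, -0.034 and 0.691 in CpG-poor, intermediate and CpG-dense sequence. The 1-division values were 0.052 over all CpGs, 5.9e-05 in CpG-poor and 0.13 at intermediate density. The >3-division values were -3.21 over all CpGs, -6.80 in CpG-poor, -3.17 at intermediate density, -0.714 in CpG-dense sequence and -5.39 on X, and -3.45 against the 0-division library. On autosomes alone the 1-division library differed by 0.082 and the >3-division library by -3.54 from control, and the latter by -3.77 from the 0-division library.

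Correlations of differences across clusters with a minimum of 20 reads were 0.491 for the 0- and 1-division, 0.279 for the 0- and >3-division and 0.226 for the 1- and >3-division libraries. Over clusters between 20% and 80% they were 0.491, 0.273 and 0.226.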

Other observations

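The hypothesis on CpG-dense neighbours was set before its result was seen, and the test on 1 Mb windows was chosen after. The clusters named here were chosen after their values were seen.

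The local losses of the >3-division library lay on all 20 chromosomes, 31 of the 831 on X. Of these clusters, 318 were CpG-poor, 418 intermediate and 95 CpG-dense. Their median level was 74.5% in control, 74.9% in the 0-division, 75.6% in the 1-division and 36.2% in the >3-division library. In 95 of them the level was over 50% in control and under 20% in the >3-division library. A cluster of 8 CpGs on chromosome 8 from 125953781 to 125953979 stood at 75.4%, 75.8%, 62.2% and 11.2% in control, 0-, 1- and >3-division cells, on 463 to 972 reads. Separate clusters on chromosome 4, at 125747365 and 125747492, stood at 72.2% and 71.0% in control and at 7.44% and 6.06% in the >3-division library. The 107 local gains had a median of 47.4% in control and 65.9% in the >3-division library. Among them a cluster of 8 CpGs on chromosome 3 from 55587445 to 55587595 stood at 38.9%, 47.8%, 40.3% and 64.6% on at least 295 reads.

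Autosomal CpG-dense clusters whose mean over control, 0- and 1-division cells lay between 35% and 65%, the range around the level that methylation on a single parental copy gives, numbered 340. They averaged 49.0% in control, 49.0% in the 0-division, 49.6% in the 1-division and 40.1% in the >3-division library. Of these, 65 lay at least 20 points below control in the >3-division library and 1 at least 20 points above. The fall in their mean was like that of all 4919 clusters at 40% to 60% in the 0- and 1-division libraries, which averaged 50.8% in control and 42.0% in the >3-division library.

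The cluster at chromosome 19, 4042274, stood at 18.4% in control and at 64.9%, 82.4% and 95.5% in the 0-, 1- and >3-division libraries, but covers 11 bp and 34 to 66 reads per library.

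Loss beside CpG islands was tested as a hypothesis and not borne out: 4.45% of the 831 lost clusters lay within 2 kb of CpG-dense unmethylated sequence, against a median of 4.45% in 1000 lists matched on control level and density (2.17% to 6.74%).

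The fall of the >3-division library in CpG-poor sequence was present in all 2534 windows of 1 Mb with at least 50 such sites, from -1.93 to -14.0 points. Whether windows with few covered CpGs lost more depended on the scale. The number of covered CpGs correlated with the log2 odds ratio (Spearman's rho = 0.374, Pearson's r = 0.301, permutation p = 0.0001, the smallest that 10000 permutations can give), and with the odds ratio against the 0-division library at rho = 0.335. The windows in the lowest quartile of CpG number had a mean odds ratio of 0.66 and those in the highest had 0.718. In points there was no such trend: the mean differences in these quartiles were -7.37 and -7.34 points, and Spearman's rho was 0.012 against control and -0.036 against the 0-division library. The hypothesis of a stronger loss in CpG-poor stretches therefore stays undecided. Windows are not replicates.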
